A study of Mus musculus with 4 samples.

How the data were processed

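The data are single-cell RNA sequencing of hippocampus and sensory cortex from wild-type mice, 1 library for each tissue and treatment (DOCA-salt or sham). Per the labels there were 3 mice per group, and whether their cells were pooled is not stated. Droplet libraries of the 3' end of transcripts were made with a SeekOne DD kit per the labels. The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode for 32285 genes. The submitters' processing notes name fastp, STAR, Subread and Seurat and the genome build GRCm38, with versions, annotation release and counting strand not given in the sources used here. No cell type annotation was used here, so cells were clustered and named again, and names can differ from those of the submitters.

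Groups were taken from the library titles. The treatment field of the labels follows tissue in every library and contradicts the title of the cortex DOCA-salt and hippocampus sham libraries. Comparisons were DOCA-salt against sham within hippocampus and within cortex, the 2 side by side, and hippocampus against cortex within each treatment. As each group held 1 library, no test was run and no p-value computed. A model of tissue and treatment without their interaction was not fitted, as it would take the 2 tissues as replicates. Ratios of UMI sums carry exact 95% intervals of counting error, conditional on the sum of the 2 counts, and shares carry exact binomial ones. A fold against 0 counts was put as a bound at a floor of 3 counts.

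Barcodes with at least 300 genes and at most 20% mitochondrial UMIs were kept, which removed 119, 163, 48 and 73 barcodes (hippocampus DOCA-salt, hippocampus sham, cortex DOCA-salt, cortex sham). All deposited barcodes held at least 500 UMIs. Scrublet as run in scanpy, at an expected rate of 0.08, removed 520, 602, 614 and 757 doublets (4.63%, 5.36%, 5.41% and 6.83%). Counts were scaled to 10000 per cell, and 2000 variable genes, 30 principal components and 15 neighbours went into Leiden clustering at resolution 1 on all libraries jointly, without batch correction. Clusters were named from 22 marker sets fixed before the data were examined, with at least 3 markers detected at 2-fold, at least 20 cells and no more markers of another class than of the own class among the 10 leading genes. Unnamed cells made up 5.42%, 3.09%, 3.27% and 5.45% of the libraries.

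Several choices were made after the data were seen. The minimum mean log2 score for a name was lowered from 1 to 0.75. It left out a cluster led by Ptprt and Pde10a, at 1.62%, 0.866%, 2.35% and 3.31% of cells, 2 low-depth clusters, at 2.47%, 0.207%, 0.186% and 0.775% (Zfp804b among the leading genes) and at 0.616%, 1.15%, 0.363% and 0.465% (Dgki, Nkain2), and a cluster led by Chst8, at 0.149%, 0.198%, 0.102% and 0.136%. Another 5 clusters of mixed markers were sub-clustered at resolution 0.5. A sub-cluster of cell cycle and neutrophil genes, with 0.0653%, 0.527%, 0.0559% and 0.0387% of cells, met the naming rule but was set to unnamed by hand. It had 4 neutrophil markers among its 10 leading genes. Left unnamed by the rule were one beside the T or NK cells, with 37, 2, 2 and 0 cells, and a vascular one led by Gkn3 and Rgs5, with 16, 13, 21 and 58 cells. Which of 18 class shares and of the gene lists lead the results, and which list and class pairs are drawn, was also picked after the values were seen.

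UMIs were summed over the cells of a class and library and scaled to counts per 1000000 UMIs (CPM). Genes were named in the 5 most frequent classes with at least 100 cells in each library. In each class and tissue these were the 3 highest and the 3 lowest by the bound of the ratio interval nearest to 1, and likewise for both tissues by the weaker of the 2 bounds. Such genes needed at least 50 UMIs and at least 0.2 of the CPM of the class with the highest level, and mitochondrial, ribosomal, haemoglobin, sex-linked and other genes set out in the same rule were not named. That rule and 35 gene lists were fixed before the data were examined. Of the lists, 34 gave a value in at least 1 class, and a list of neutrophil granule genes gave none because 1 library held too few cells. A list's median log2 ratio was taken over members with at least 20 UMIs, with an interval from 1000 Poisson redraws and a percentile among 10000 lists of random genes from 20 bins of level. These percentiles describe the libraries and are not p-values. Genes were matched to GENCODE vM21 coordinates, 32158 of them.

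Signs of background were read from lists of RNA foreign to a class. Astrocyte RNA had medians of 0.89 and 0.47 in microglia-like, 0.87 and 0.20 in endothelial-like and 0.66 and 0.43 in oligodendrocyte-like cells of hippocampus and cortex. That list also holds Ttr, a choroid plexus transcript, and Apoe, which is in the disease-associated microglia list too, so not all of it is foreign astrocyte RNA. Myelin RNA had medians of -0.82 and -0.02 in microglia-like and -0.27 and -0.10 in endothelial-like cells, with -0.87 in hippocampal endothelial-like cells without clusters held by 1 library. Haemoglobin RNA lay at 0.70 and 0.57 in microglia-like and 0.97 and 0.18 in endothelial-like cells, and neuronal RNA at 0.22 and 0.23 in microglia-like cells, but at -0.51 in hippocampus with a minimum of 100 UMIs and -0.49 after thinning. Sex-linked genes lay at -0.08 and -0.05 in microglia-like cells. Iglc1 stood at 198.8 CPM over all cells of the hippocampus sham library and 2.91 CPM in the DOCA-salt one. Per3 held 0 UMIs in all libraries and was left out of the clock genes.

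The alternatives tried were stricter filtering (1000 UMIs, 500 genes, 10% mitochondrial UMIs), no filter, doublets kept, resolutions 0.5 and 2, libraries clustered alone, shares among immune or non-immune cells, TMM scaling, totals without mitochondrial, ribosomal and haemoglobin genes, equal weight per cell, cells thinned to 1000 UMIs, and list minimums of 100 UMIs or none (pseudocount 0.5). Thinning left out 696, 432, 365 and 382 shallower cells. Alternatives added after seeing the data were no sub-clustering, the neutrophil class with the mixed cycling cluster, and classes without clusters of which 1 library held at least 90%. The calculation was tested on simulated data with 200 altered genes. Intervals held the true ratio for 95.6% of 12852 genes at the depth of hippocampal oligodendrocytes and for 95.9% of 9854 genes at that of endothelial cells. At 1.5-fold the interval excluded no difference for 90.0% and 79.7% of altered genes and at 2-fold for 98.6% and 97.1%, which is the precision the depth gives. The simulated sums were Poisson counts, so this check leaves out the spread between cells. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9 and edgeR 4.0.16 under R 4.3.3.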

Results

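Single cells from the hippocampus and the sensory cortex of wild-type mice were sequenced after DOCA-salt treatment, in which a mineralocorticoid and salt raise blood pressure, or after sham treatment. There were 4 libraries, 1 for each tissue and treatment. The labels give 3 mice per group and do not say whether their cells were pooled. The deposited matrices held 11360 barcodes with 67745118 UMIs (hippocampus, titled DOCA-salt), 11394 with 70173987 (hippocampus, titled sham), 11402 with 66824217 (cortex, titled DOCA-salt) and 11159 with 68152808 (cortex, titled sham). After filtering, 10721, 10629, 10740 and 10329 cells remained, at a median of 5855, 5761, 5541 and 5761 UMIs per cell. For the cortex library titled DOCA-salt and the hippocampus library titled sham, the treatment field of the labels names the opposite treatment. Groups follow the titles, so every direction between treatments rests on them, and if the field were right both hippocampus libraries would be DOCA-salt and both cortex libraries sham. No comparison within a tissue would then be one of treatment, and tissue and treatment could not be separated. With 1 library per group no test within a tissue was possible and none was run, and all intervals are 95% intervals of counting error only: they hold neither the spread between animals nor that between library preparations. Intervals of UMI ratios take each UMI as independent, so they also leave out the spread between cells of a library.

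The first comparison asked how the cells of the hippocampus differ between DOCA-salt and sham. The hippocampus DOCA-salt library held larger shares of 4 kinds of blood-derived leukocyte: B-cell-like, T- or NK-cell-like, monocyte-like and neutrophil-like cells. Astrocyte-like cells also took a larger share, while oligodendrocyte-like cells, their precursors, immature neurons and smooth-muscle-like cells took smaller ones. Macrophages of the brain borders were about equally frequent in both libraries in the joint clustering. B-cell-like cells, carrying immunoglobulin genes, made up 0.578% of cells (62 cells, 0.444 to 0.741) against 0.207% (22 cells, 0.130 to 0.313), 2.79 times the sham share (1.69 to 4.77). Monocyte-like cells, whose cluster was led by the MHC class II genes H2-Eb1, H2-Aa, H2-Ab1 and Cd74, stood at 75 against 31 cells, 2.40 times (1.56 to 3.77). Of the monocyte markers only Plac8 was among the 10 leading genes of that cluster, beside the dendritic cell genes Napsa and Ccl17, so dendritic cells can be part of it. T- or NK-cell-like cells stood at 75 against 41 cells, 1.81 times (1.22 to 2.72), beside an unnamed cluster led by Ccl5 with 37 against 2 cells. Neutrophil-like cells, defined by neutrophil genes such as S100a8 and S100a9, numbered 42 (0.392%) against 4 (0.0376%), 10.4 times (3.78 to 39.97). A cluster led by neutrophil genes (Camp, Elane, Ngp, S100a8) and cell cycle genes (Ube2c, Top2a, Cenpf) met the naming rule but was left out by hand. It held 7 against 56 cells (0.0653% and 0.527%), and counting it as neutrophil turned the ratio to 0.810 times. In its 56 sham cells S100a8 and S100a9 were found in 0 and Cenpf in 32, while all 42 and 4 neutrophil-like cells carried S100a8. S100a8 RNA was spread over other cells of the same library, at 49.7 against 2.0 counts per 1000000 UMIs (CPM) in microglia-like cells. Border-macrophage-like cells stood at 1.001 times (0.760 to 1.32), but at 0.754 times with each library clustered alone. Microglia-like cells stood at 25.2% against 22.4%, 1.12 times (1.06 to 1.19), but at 0.958 times among immune cells alone. Haemoglobin RNA, from blood left in the tissue, was also higher in the DOCA-salt library: Hbb-bs reached 6031 against 3135 CPM over all cells. Erythroid-like cells, at 1.21 times the sham share (0.901 to 1.62), held 343206 of its 382028 UMIs in the DOCA-salt library. In pericyte-like cells it went the other way, at 761 against 7292 CPM.

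Among cells of neural and vascular origin in the hippocampus, astrocyte-like cells made up 15.2% against 8.12%, 1.87 times the sham share (1.72 to 2.03). Oligodendrocyte-like cells made up 33.8% against 45.2%, 0.747 times (0.715 to 0.780). When each library was clustered alone this ratio was 1.18, with 2020 cells of the sham library and 78 of the DOCA-salt library then without a name (328 and 581 in the joint clustering). Oligodendrocyte precursors stood at 0.551 times (0.354 to 0.846, 35 against 63 cells) and immature neurons at 0.474 times (0.321 to 0.689, 43 against 90 cells). Endothelial-like cells stood at 1.22 times (1.11 to 1.33) and pericyte-like cells at 1.23 times (1.05 to 1.44). For pericyte-like cells the ratio was 1.01 with coarser clusters and 1.04 without sub-clustering. Smooth-muscle-like cells, the contractile cells of arterioles, stood at 0.237 times (0.140 to 0.384, 21 against 88 cells), and at 0.907 times without the sub-clustering that separated them from pericytes. Choroid plexus epithelium gave 2 against 348 cells, so the hippocampus sham dissection took in choroid plexus. Its transcript Ttr followed into other cells, at 29.98 against 3802 CPM in microglia-like cells.

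In the sensory cortex the same question gave the same order for 3 leukocyte classes and another for neutrophils. B-cell-like cells stood at 32 against 12, 2.56 times the sham share (1.29 to 5.47), T- or NK-cell-like cells at 48 against 25, 1.85 times (1.12 to 3.13), and monocyte-like cells at 45 against 23, 1.88 times (1.11 to 3.26). Neutrophil-like cells numbered 9 in both libraries, 0.962 times (0.338 to 2.73). Border-macrophage-like cells stood at 1.10 times (0.772 to 1.57) and microglia-like cells at 0.921 times (0.871 to 0.974). Smooth-muscle-like cells were again fewer, at 0.350 times (0.218 to 0.545, 28 against 77 cells), with 0.562 times without sub-clustering and 0.218 times under a stricter cell filter. Oligodendrocyte precursors stood at 0.334 times (0.180 to 0.590, 17 against 49 cells). Astrocyte-like cells stood at 1.19 times (1.14 to 1.25), oligodendrocyte-like cells at 0.943 times (0.895 to 0.994) and endothelial-like cells at 0.9001 times (0.808 to 1.003). Pericyte-like cells stood at 1.41 times (1.17 to 1.69), but at 0.971 times with coarser clusters. Hbb-bs was at 2754 against 2480 CPM over all cells. Immature neurons numbered 14 in both libraries.

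**Figure D1:**
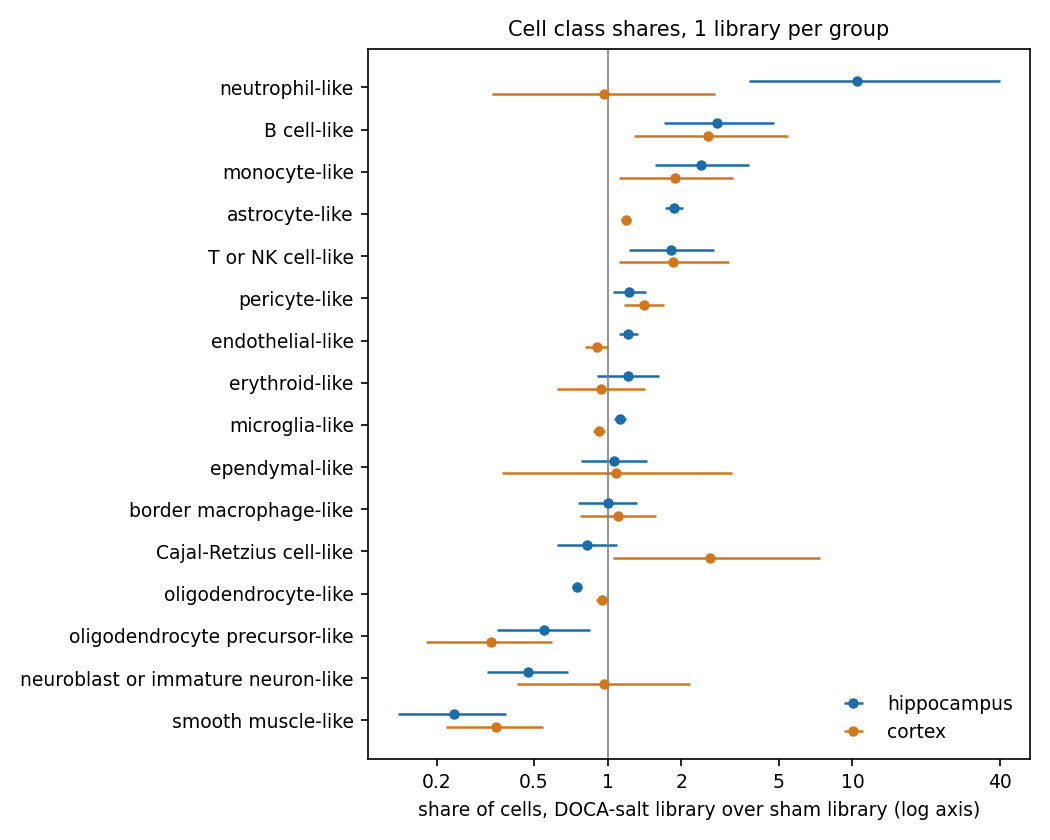
Ratio of the share of a class of cells in the library titled DOCA-salt to that in the library titled sham, with exact 95% intervals of counting error. Choroid plexus epithelium, fibroblast-like cells and unnamed cells are not drawn. Neutrophil-like cells stood at 10.4 times the sham share in hippocampus and 0.962 times in cortex.

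Endothelial-like cells of the DOCA-salt libraries carried more RNA of adhesion and acute-phase genes in both tissues, and less RNA of interferon-stimulated genes. Transcripts of the barrier itself stayed close to the sham level, apart from 2 transporters. Of 11 measured members of the endothelial activation list, 9 were at least 1.5-fold higher in the hippocampus DOCA-salt library and 5 in the cortex one, with 0 at least 1.5-fold lower in either. The median log2 ratio was 0.91 in hippocampus (0.78 to 1.21) and 0.55 in cortex (0.46 to 0.86), both above all 10000 random lists, and 1.30 in cortex with no minimum of UMIs. Such percentiles are a description of these libraries, not a test. Lcn2 (ENSMUSG00000026822; chromosome 2, 32384633 to 32388252 on GRCm38), which encodes the iron-scavenging lipocalin 2, was 35.4-fold higher in hippocampus (21.6 to 62.3; 164 against 4.63 CPM) and 16.9-fold in cortex (11.1 to 27.0; 129.8 against 7.68 CPM). Lrg1, encoding a secreted glycoprotein that acts on vessels, was 19.8-fold (11.4 to 37.6) and 20.5-fold (10.5 to 45.6) higher. Ackr1 (ENSMUSG00000037872; chromosome 1, 173331886 to 173333750), encoding the atypical chemokine receptor of venules, was 175-fold higher in hippocampus (31.1 to 6950) and 111-fold in cortex (19.4 to 4408), each against 1 UMI in the sham library (log2 ratio 5.81 in cortex with equal weight per cell). Vcam1, the adhesion molecule that lymphocytes bind, was 4.10-fold (3.37 to 5.03) and 1.47-fold (1.23 to 1.75) higher, Icam1 1.78-fold and 1.34-fold, and Vwf, the clotting factor stored by endothelium, 2.21-fold and 2.39-fold. A cluster led by Lcn2 and Vwf held 74 endothelial-like cells of the hippocampus DOCA-salt library and 1 other cell. Without it Lcn2 was still 33.1-fold higher in hippocampus (20.2 to 58.3). S100a8, from neutrophils, was at 89.4 against 1.16 CPM in these hippocampal cells.

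The inflammatory and NF-kB list had a median of 0.37 in hippocampal and 0.42 in cortical endothelial-like cells, with Il1b 5.26-fold (2.36 to 13.8) and 3.68-fold (1.43 to 11.2) higher and Ptgs2, which encodes cyclooxygenase 2, 2.43-fold and 4.49-fold. Il1b was also a leading gene of a microglial cluster, and whether its RNA here came from other cells was not tested. The type I interferon list went the other way: 13 of 19 members in hippocampus and 12 of 19 in cortex were at least 1.5-fold lower in the DOCA-salt library, 0 at least 1.5-fold higher, at medians of -0.72 (-0.85 to -0.63) and -0.85 (-0.93 to -0.67), both below all random lists. Ifit1 stood at 0.431 and 0.516 times the sham level, Isg15 at 0.555 and 0.439 times, and Bst2, which tethers enveloped viruses, at 0.505 and 0.494 times. Interferon gamma response genes had medians of -0.29 and -0.21. The blood-brain barrier list lay at -0.02 and -0.10, with the tight-junction gene Cldn5 at 1.01 and 1.02 times the sham level. Slc2a1, which encodes the glucose transporter of the barrier, stood at 0.655 (0.636 to 0.675) and 0.598 times (0.578 to 0.619), and the amino acid transporter gene Slc7a5 at 0.647 and 0.564 times. The hypoxia list had medians of 0.31 and 0.56. Its member Ankrd37 (ENSMUSG00000050914), a target of hypoxia-inducible factor, was among the genes named by size, 2.34-fold (2.06 to 2.66) and 3.50-fold (2.93 to 4.20) higher. The same rule named Zbtb16 (ENSMUSG00000066687), 8.24-fold (6.09 to 11.4) and 7.53-fold lower (5.27 to 11.1), and Map3k6 (ENSMUSG00000028862), a stress-activated kinase gene, 3.46-fold (2.51 to 4.85) and 4.55-fold lower (3.06 to 6.98). It also named Cd59b (ENSMUSG00000068686), 10.6-fold and 7.99-fold higher, and Cd59a (ENSMUSG00000032679), 3.22-fold and 3.43-fold lower. These paralogs lie side by side on chromosome 2 and reads can pass from one to the other, so both directions are uncertain. After thinning, cortical endothelial-like cells gave log2 ratios of 2.29 for Cd59b and -3.50 for Zbtb16. Pericyte-like cells showed Cd59b 6.01-fold higher in hippocampus (log2 ratio 3.58 after thinning) and Cd59a 3.03-fold and 3.36-fold lower.

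Oligodendrocyte-like cells, which make myelin, differed in genes of acute response and little in those of myelin. Of 19 immediate early genes, 14 were at least 1.5-fold higher in the DOCA-salt library in each tissue, at medians of 0.81 in hippocampus and 0.79 in cortex, above all random lists. Fos was 3.07-fold (3.00 to 3.13) and 4.93-fold (4.80 to 5.07) higher, Dusp1 2.31-fold and 3.90-fold, Junb 2.27-fold and 2.49-fold. Such genes also answer to dissociation of the tissue, which was not measured here. The acute-phase protease inhibitor gene Serpina3n (ENSMUSG00000021091; chromosome 12, 104406729 to 104414329) stood at 60.8 against 5.34 CPM in hippocampus, 11.4-fold higher (9.72 to 13.4), and at 68.4 against 5.82 CPM in cortex, 11.7-fold (9.61 to 14.5). Complement gene C4b was 2.09-fold (1.84 to 2.38) and 3.91-fold (3.40 to 4.51) higher, within a disease-associated oligodendrocyte list at medians of 0.21 and 0.38. MHC class I presentation genes had medians of 0.41 and 0.58, with H2-D1 1.40-fold and 1.46-fold higher. Zfp804b (ENSMUSG00000092094), a zinc-finger gene, was 95.5-fold (64.9 to 147) and 34.5-fold (23 to 54.2) higher, and Neb (ENSMUSG00000026950), which encodes the muscle protein nebulin, 84.4-fold (32.5 to 312) and 35.1-fold (13.4 to 131). Without clusters held by 1 library the log2 ratio of Neb in hippocampus was 5.64, and thinning gave 5.90 for Zfp804b in cortex. An unnamed cluster with Zfp804b among its leading genes, at a low median of 775 UMIs, held 265 cells (2.47%) of the hippocampus DOCA-salt library and 22 (0.207%) of the sham one.

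Lower in oligodendrocyte-like cells of both DOCA-salt libraries were Zbtb16 (chromosome 9, 48654297 to 48836222), a transcription factor gene induced by corticosteroids, 5.10-fold (4.67 to 5.57) and 6.53-fold (5.77 to 7.43), Sgk1 (ENSMUSG00000019970), the kinase gene under mineralocorticoid and glucocorticoid control, 2.34-fold (2.28 to 2.39) and 2.19-fold (2.12 to 2.26), and Polr3e (ENSMUSG00000030880), encoding a subunit of RNA polymerase III, 2.35-fold and 2.32-fold. Fkbp5 (ENSMUSG00000024222), a classic glucocorticoid receptor target, was 3.46-fold lower in hippocampus (2.93 to 4.10) and stood at 0.318 times in cortex. Named in 1 tissue only were Ighg1 (ENSMUSG00000076614), at 344 against 0 UMIs in hippocampus, at least 155-fold at a floor of 3 counts, and Fabp12 (ENSMUSG00000027530), 4.30-fold lower there. In cortex they were Myh8 (ENSMUSG00000055775), 69.0-fold higher at 62 against 1 UMI (11.9 to 2769), Cntnap5c (ENSMUSG00000038048), 4.28-fold lower, and Haglr (ENSMUSG00000075277), 4.89-fold lower. In cells thinned to an equal depth the last 2 shrank to log2 ratios of -0.85 and -0.38 (Haglr -2.96 with finer clusters), while hippocampal Fkbp5 and Fabp12 went to -2.45 and -2.82. Ighg1 stood at 15.6 CPM over all cells of the hippocampus DOCA-salt library, a level inside the interval of each named class there, B-cell-like cells (17.6 CPM, 4.80 to 45.1) included, which is the pattern of background RNA. Myelin genes had medians of -0.10 and -0.15 (percentiles 1.35 and 0.2 of random lists) with 0 of 13 beyond 1.5-fold. Different clusters held most of the class in the hippocampus libraries: cluster 0 gave 57.1% of it under DOCA-salt, and cluster 5, with Cryab and Polr3e among its leading genes, gave 2732 of 4806 cells under sham but 63 under DOCA-salt. Cell cycle genes Prc1 and Tpx2 led 2 small oligodendrocyte sub-clusters, 1 of them with Top2a.

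Astrocyte-like cells carried more Serpina3n and immediate early RNA in both DOCA-salt libraries, with smaller differences in reactive gene lists, while Gfap stayed near the sham level. Serpina3n was 8.02-fold higher in the hippocampus DOCA-salt library (5.73 to 11.6; 58.8 against 7.33 CPM) and 14.4-fold in cortex (11.5 to 18.3). Gfap, the structural marker of reactive astrocytes, stood at 1.15 (1.08 to 1.23) and 0.919 times (0.868 to 0.973) the sham level. The pan-reactive list had medians of 0.30 and 0.12 (percentiles 98.8 and 73.9 of random lists), the neurotoxic (A1) list 0.32 and 0.31 (98.1 and 95.5), the A2 list 0.34 and 0.41, and the homeostasis list 0.01 and -0.07. Complement genes had medians of 0.27 and 0.30 and MHC class I genes 0.32 and 0.30. Immediate early genes were higher here too, 12 of 18 members in hippocampus and 12 of 19 in cortex by at least 1.5-fold, at medians of 0.67 and 0.61, with Fos 2.28-fold and 2.92-fold. The gene named as lowest in both tissues was Pde10a (ENSMUSG00000023868; chromosome 17, 8525372 to 8986648), encoding a cyclic nucleotide phosphodiesterase, 13.3-fold (11.4 to 15.5) and 14-fold lower (12.6 to 15.6). Pde10a also led an unnamed cluster of 174 and 92 hippocampal and 252 and 342 cortical cells, and over all cells it was still lower, at 6.73 against 25.5 CPM and 9.06 against 95.5 CPM. Next came Zbtb16, 3.77-fold (3.17 to 4.49) and 4.15-fold lower (3.67 to 4.70), and Tsc22d3 (ENSMUSG00000031431), which encodes the glucocorticoid-induced leucine zipper, 3.02-fold (2.83 to 3.22) and 3.46-fold lower (3.33 to 3.59). Bricd5 (ENSMUSG00000045744) was 8.03-fold (5.17 to 13.1) and 8.28-fold (6.55 to 10.6) higher, and Fshr (ENSMUSG00000032937), encoding the receptor of follicle-stimulating hormone, 12.2-fold (3.20 to 103, 2 sham UMIs) and 32.2-fold (12.3 to 120). Ighg1 (at least 25.1-fold in hippocampus) and Myh8 (72 against 0 UMIs in cortex, at least 21.5-fold) were named in 1 tissue. When cells were thinned to an equal depth, Serpina3n and Bricd5 in hippocampal astrocytes gave log2 ratios of 4.16 and 2.31. Myelin RNA in these cells, which is background, had medians of -0.87 in hippocampus and -0.08 in cortex.

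Microglia-like cells, the resident macrophages of brain tissue, showed fewer heat shock transcripts in both DOCA-salt libraries and no loss of identity genes beyond 1.5-fold. Heat shock genes had medians of -0.52 and -0.62, below all random lists, with 5 and 7 of 13 members at least 1.5-fold lower: Hspa1b stood at 0.470 and 0.450 times the sham level and the chaperone gene Hsph1 at 0.566 and 0.501 times. In oligodendrocyte-like cells that list lay at -0.35 and -0.29, in endothelial-like cells at -0.27 and -0.32 and in astrocyte-like cells at -0.11 and -0.28. Homeostatic microglia genes had medians of -0.08 and -0.20 (percentiles 2.97 and 0.07 of random lists), a small shift downward as a set. Of them 0 of 12 went beyond 1.5-fold, with Tmem119 at 0.797 and 0.679 times and P2ry12 at 0.922 and 0.876 times. Disease-associated microglia genes had medians of 0.12 and 0.14, MHC class I genes 0.15 and 0.11, and MHC class II genes 0.33 and 0.29, with H2-Aa 2.35-fold (1.85 to 3.02) and 1.63-fold (1.17 to 2.28) higher. Inflammatory and NF-kB genes had medians of -0.00 and 0.22: Tnf was 1.21-fold and 1.61-fold higher, Il1b 1.43-fold and 1.47-fold. The type I interferon list lay at -0.11 and -0.10, yet in hippocampus Ifit1 stood at 0.357 times (0.330 to 0.386), Ifit3 at 0.343 times (0.292 to 0.402) and Isg15 at 0.530 times. The largest microglial cluster differed by library: cluster 3 under DOCA-salt in hippocampus (50.2%) and under sham in cortex (41.2%), cluster 4 under sham in hippocampus (50.8%), led by Ifnb1, Cxcl10 and Ifit1, and cluster 7 under DOCA-salt in cortex (43.7%), led by Gpr84, Il1a and Il1b.

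By the size rule, microglia-like cells of both DOCA-salt libraries were higher in Cntn4 (ENSMUSG00000064293), a neural adhesion gene, 29.7-fold (19.8 to 46.5) and 34.4-fold (23.3 to 53.0), in Slc15a2 (ENSMUSG00000022899; chromosome 16, 36750177 to 36784962), encoding the peptide transporter PEPT2, 26.9-fold (22.1 to 33; 213 against 7.93 CPM) and 13.4-fold (11.8 to 15.4; 213 against 15.8 CPM), and in the chemokine receptor gene Ccr6 (ENSMUSG00000040899), 13-fold (10.8 to 15.9) and 14.2-fold (11.5 to 17.9). They were lower in Upk1b (ENSMUSG00000049436), 3.84-fold (3.34 to 4.42) and 5.0-fold (4.38 to 5.72), in Fblim1 (ENSMUSG00000006219), which encodes an adaptor of cell adhesion sites, 3.62-fold (2.87 to 4.58) and 3.48-fold (2.80 to 4.35; log2 ratio -2.40 after thinning), and in C5ar2 (ENSMUSG00000074361), encoding a second receptor of complement C5a, 2.25-fold (1.95 to 2.59) and 2.58-fold (2.22 to 3.02). Named in 1 tissue only, Adamts13 (ENSMUSG00000014852) was 9.98-fold lower in hippocampus (4.53 to 26.0), Ighg1 219-fold higher there (38.9 to 8669, 1 sham UMI; log2 ratio 8.99 with equal weight per cell) and Dpys (ENSMUSG00000022304) 107-fold higher in cortex (36.3 to 522, 317 against 3 UMIs), with Dpys at 6.19 against 0 CPM in hippocampus. Slc1a2, an astrocyte transcript, gauged background in microglia-like cells: 132 against 63.1 CPM in hippocampus and 326 against 241 CPM in cortex.

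Border-macrophage-like cells, the macrophages of meninges and vessel spaces, carried more MHC class II RNA in the DOCA-salt libraries, at a similar share of cells in the joint clustering. In both tissues 6 of 7 measured members were at least 1.5-fold higher, with medians of 1.32 (0.78 to 1.66) in hippocampus and 3.31 (2.88 to 3.86) in cortex, or 2.64 there with no minimum of UMIs. Cd74, the invariant chain, was 2.79-fold (2.27 to 3.47) and 9.94-fold (7.04 to 14.5) higher. H2-Aa was 4.20-fold (2.57 to 7.20) higher in hippocampus and 41.6-fold (11.2 to 348) in cortex, where the sham library held 2 UMIs of it. The class numbered 71 and 62 cells in cortex and 109 and 108 in hippocampus. The monocyte-like cells, rich in the same genes, were also more frequent, and a few of them inside this class would raise these values. Type I interferon genes had medians of 0.30 in hippocampus and -0.76 in cortex, where Isg15 stood at 0.215 times (0.128 to 0.348). Interferon gamma response genes had medians of 0.11 (-0.21 to 0.47) in hippocampus and -0.48 (-0.87 to -0.08) in cortex. In T- or NK-cell-like cells the cytotoxic and effector list lay at -0.27 (-0.47 to 0.02) and -0.45 (-0.70 to 0.06), intervals that include no difference, with 3 members higher and 3 lower by at least 1.5-fold in hippocampus and 2 and 4 in cortex. In these cells Cd69 was 1.58-fold and 1.93-fold higher and Cxcr6, a receptor of tissue-resident lymphocytes, at 0.482 and 0.484 times the sham level.

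Targets of the corticosteroid receptors tended to be lower in the DOCA-salt libraries, with an interval that included no difference in cortical endothelial-like cells and, after thinning, in hippocampal microglia-like cells. The list had medians of -0.50 (-0.66 to -0.40) and -0.57 (-0.69 to -0.38) in oligodendrocyte-like cells of hippocampus and cortex, -0.52 (-0.64 to -0.38) and -0.22 (-0.37 to -0.16) in astrocyte-like, and -0.24 (-0.37 to -0.15; -0.061, -0.24 to 0.029, after thinning) and -0.23 (-0.40 to -0.07) in microglia-like cells. They were -0.56 (-0.75 to -0.33) and -0.19 (-0.51 to 0.02; -0.41, -0.63 to -0.16, after thinning) in endothelial-like and -0.29 (-0.48 to -0.13) and -0.26 (-0.45 to -0.06) in pericyte-like cells. All 10 medians were negative, and all lay below the 1st percentile of random lists. Of the members, 7 and 8 of 16 were at least 1.5-fold lower in oligodendrocyte-like cells and 2 higher in each tissue: Pdk4 was 1.84-fold and 1.92-fold higher and the metallothionein gene Mt2 1.60-fold and 1.78-fold. At least 1.5-fold lower were also 7 and 6 of 16 members in astrocyte-like (0 and 2 higher, Errfi1 and Pdk4 in cortex), 4 and 5 of 16 in microglia-like, 8 of 16 and 4 of 15 in endothelial-like and 4 of 14 and 3 of 13 in pericyte-like cells. Tsc22d3 in endothelial-like cells stood at 0.415 (0.379 to 0.453) and 0.391 times (0.349 to 0.438) the sham level, and Fkbp5 at 0.343 (0.159 to 0.696) and 0.221 times (0.0752 to 0.540). Sgk1 there stayed at 0.939 (0.859 to 1.03) and 1.02 times (0.920 to 1.14). In pericyte-like cells Zbtb16 was 9.93-fold (5.59 to 19.2) and 7.64-fold lower (4.21 to 15), with log2 ratios in hippocampus of -4.03 at equal weight per cell and -2.66 at coarser clusters.

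**Figure D2:**
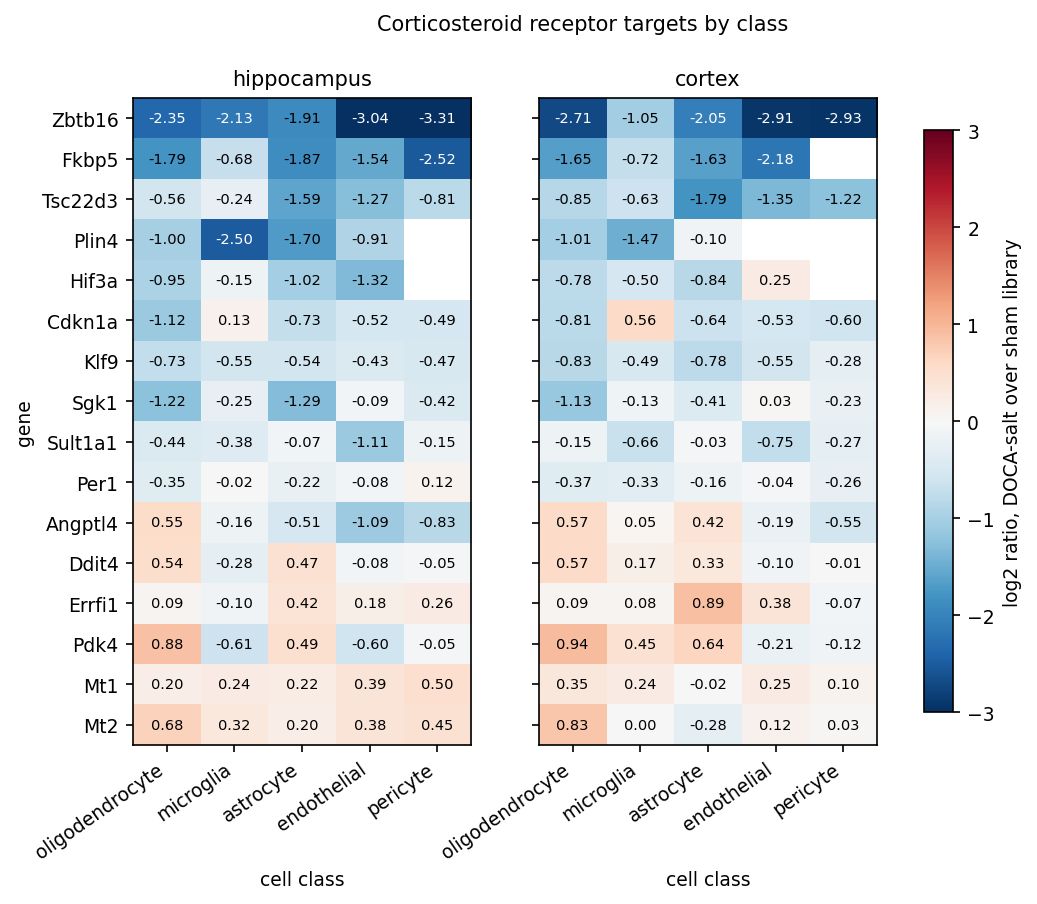
Log2 ratio of DOCA-salt to sham for the 16 members of the corticosteroid receptor target list in 5 classes and both tissues, ordered by their median, with cells under 20 UMIs left blank. Zbtb16 was 9.93-fold lower in hippocampal pericyte-like cells.

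Pericyte-like cells, which wrap capillaries, also carried less Cthrc1 (ENSMUSG00000054196), a gene of collagen deposition, 3.54-fold (2.68 to 4.73) and 4.78-fold lower (3.19 to 7.36), with a log2 ratio of -2.90 in cortex after thinning and -3.02 at equal weight per cell. Higher in both tissues were Vwf (ENSMUSG00000001930), 1.85-fold (1.53 to 2.25) and 2.27-fold (1.74 to 3.00), Ankrd37, 1.84-fold (1.46 to 2.34) and 3.58-fold (2.41 to 5.46), and the clock output gene Dbp (ENSMUSG00000059824), 1.78-fold (1.45 to 2.18) and 1.94-fold (1.52 to 2.51). Vwf is an endothelial gene, so endothelial RNA or mixed cells can carry it here, and thinning left a log2 ratio of 0.58 in cortex. Pericyte sub-clusters with pericyte scores of 5.08 and 3.88 had endothelial as their second class, at 2.88 and 3.28. Lcn2 stood at 95.2 against 5.51 CPM in hippocampal and 68.4 against 2.94 CPM in cortical pericyte-like cells. Endothelial RNA can thus also add to Ankrd37, Cd59b, Cd59a and Zbtb16 in this class, which was not tested. In hippocampus alone the rule named Myof (ENSMUSG00000048612), 3.49-fold (1.77 to 7.52), with a log2 ratio of 0.96 at coarser clusters and 0.98 without sub-clustering, and Rtn4rl1 (ENSMUSG00000045287), 2.35-fold. In cortex alone it named Rabgef1 (ENSMUSG00000025340), 4.19-fold (2.65 to 6.95), with a log2 ratio of 0.49 after thinning. Haemoglobin RNA in pericyte-like cells was lower in the DOCA-salt libraries, unlike that over all cells. Hbb-bs stood at 761 against 7292 CPM in hippocampus and 321 against 3047 CPM in cortex. Whether the sham pericyte-like cells include mixtures with red blood cells was not tested. Vasoactive signalling genes had medians of -0.14 and -0.06, with Edn1, the endothelin 1 gene, at 0.540 and 0.651 times the sham level, and extracellular matrix genes lay at -0.04 and -0.10. In endothelial-like cells the vasoactive list lay at 0.21 and -0.00 and the matrix list at -0.15 and -0.25.

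**Figure D3:**
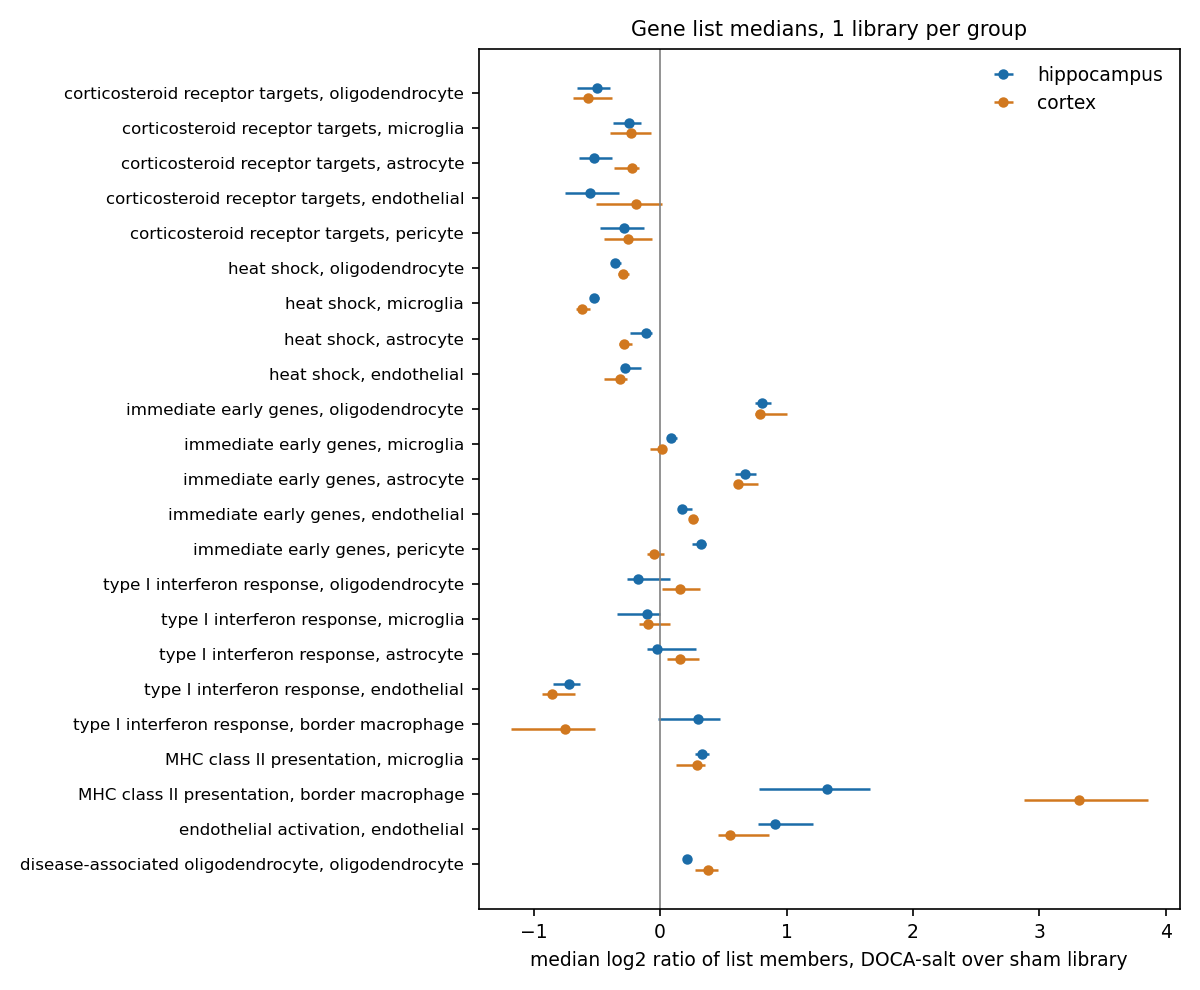
Median log2 ratio of DOCA-salt to sham for 23 pairs of gene list and class, with intervals of counting error, chosen after the medians were seen. MHC class II genes in cortical border-macrophage-like cells had the highest median, 3.31.

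Hippocampus set beside cortex asked whether the treatment difference was the same in both tissues. Serpina3n, Zbtb16, Slc15a2 and Pde10a pointed the same way in both, but the rule that named them for both tissues asks for that, so they do not answer the question. Of the shares, those of microglia-like (1.12 times in hippocampus, 0.921 in cortex), endothelial-like (1.22 and 0.9001), astrocyte-like (1.87 and 1.19) and oligodendrocyte-like cells (0.747 and 0.943) had intervals that did not overlap between tissues. Among immune cells alone microglia-like cells stood at 0.958 and 0.970 times, which ends their difference, and with each library clustered alone oligodendrocyte-like cells stood at 1.18 and 0.893 times, which turns theirs. The cortical interval of immature neurons (0.425 to 2.18) held the hippocampal ratio of 0.474, so their share does not settle it. Neutrophil-like cells also had intervals that did not overlap (10.4 and 0.962 times), from 4 sham cells in hippocampus. The mixed cluster that turned the hippocampal ratio does not count against this, as S100a8 and S100a9 were found in 0 of its 56 sham cells and in all neutrophil-like cells. Among class shares, gene list members and genes named in 1 tissue, opposite directions of at least 1.5-fold, with intervals clear of no difference, appeared for 4 genes: Ccl4 in border-macrophage-like cells (0.559 times in hippocampus, 2.41 times in cortex), Ccn2 in pericyte-like cells (0.457 and 3.26 times), Gzma in T- or NK-cell-like cells (3.88 and 0.381 times) and Ttr in microglia-like cells (0.00789 and 1.61 times). Genes outside that search went apart too, such as Lcn2 in the neutrophil-like cells (7632 against 1177 CPM in hippocampus, from 42 and 4 cells, and 1782 against 16660 CPM in cortex). The difference between tissues was not tested.

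The last comparison set hippocampus against cortex within each treatment, and named genes that pointed the same way in both, as its rule asks. Not all classes kept their order: microglia-like cells stood at 0.914 times the cortical share under sham (0.864 to 0.967) and 1.12 times under DOCA-salt (1.06 to 1.18), and neutrophil-like cells at 0.432 (0.0972 to 1.55) and 4.67 times (2.24 to 10.9). Hippocampus held more Cajal-Retzius-like cells, 15.8 times the cortical share under sham (7.44 to 40.3) and 5.01 times under DOCA-salt, more ependymal-like cells, 10.3 and 10.1 times, and more immature neurons, 6.25 and 3.08 times. Cortex held more astrocyte-like cells, so hippocampus stood at 0.270 and 0.424 times. Oligodendrocyte-like cells stood at 1.62 and 1.28 times and endothelial-like cells at 1.19 and 1.60 times. Regional genes marked the astrocyte-like cells most: Six3 (ENSMUSG00000038805), a homeobox gene of the forebrain, was 19.4-fold lower in hippocampus under sham (8.23 to 59.9) and at 0 against 730 UMIs under DOCA-salt, at least 106-fold. The overlapping transcript Six3os1 (ENSMUSG00000093460) was 21.5-fold lower under sham, with 3 hippocampal UMIs, and at least 68.2-fold lower under DOCA-salt. The strand used for counting is not stated, so reads can be shared and the split between the 2 genes is uncertain. Rpe65 (ENSMUSG00000028174) was 8.68-fold and 6.45-fold lower. Thbs4 (ENSMUSG00000021702), a thrombospondin gene, was 8.94-fold and 6.11-fold higher, Siah3 (ENSMUSG00000091722) 7.62-fold and 14.4-fold, and the Wnt antagonist gene Frzb (ENSMUSG00000027004) 6.31-fold and 9.30-fold.

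In microglia-like cells the hippocampus was higher in Klf4 (ENSMUSG00000003032), 1.72-fold under sham and 1.75-fold under DOCA-salt, Gadd45g (ENSMUSG00000021453), 2.01-fold and 1.73-fold, and Tmx4 (ENSMUSG00000034723), 1.66-fold and 1.93-fold. It was lower in Trib1 (ENSMUSG00000032501), 1.78-fold and 1.92-fold, Etv3 (ENSMUSG00000003382), 1.76-fold and 1.79-fold, and the cell cycle kinase gene Cdk6 (ENSMUSG00000040274), 1.71-fold and 1.90-fold. Oligodendrocyte-like cells of hippocampus were higher in Btc (ENSMUSG00000082361), the betacellulin gene, 3.25-fold and 3.97-fold, Tmem132d (ENSMUSG00000034310), 1.90-fold and 1.92-fold, and the nuclear RNA Neat1 (ENSMUSG00000092274), 1.74-fold and 1.76-fold. They were lower in the protease gene Klk6 (ENSMUSG00000050063), 2.28-fold and 3.38-fold, Shisa8 (ENSMUSG00000096883), 1.46-fold and 1.73-fold, and Zfp467 (ENSMUSG00000068551), 1.40-fold and 1.60-fold. Endothelial-like cells of hippocampus were higher in Stra6 (ENSMUSG00000032327), the retinol transporter gene, 2.06-fold and 2.11-fold, Klf2 (ENSMUSG00000055148), which responds to blood flow, 1.65-fold and 1.36-fold, and Rhob (ENSMUSG00000054364), 1.32-fold and 1.31-fold. They were lower in Cpe (ENSMUSG00000037852), 5.55-fold and 3.08-fold, Fads1 (ENSMUSG00000010663), 2.73-fold and 2.44-fold, and Fam107a (ENSMUSG00000021750), 1.72-fold and 2.24-fold. Pericyte-like cells of hippocampus were higher in Ddc (ENSMUSG00000020182), 2.19-fold and 1.94-fold, Klf2, 1.5-fold and 1.64-fold, and Plk2 (ENSMUSG00000021701), 1.70-fold and 1.53-fold, and lower in Slc1a2 (ENSMUSG00000005089), 8.22-fold and 4.27-fold, Cpe, 5.6-fold and 3.50-fold, and Ndrg2 (ENSMUSG00000004558), 3.73-fold and 3.24-fold. Slc1a2 is an astrocyte transcript, at 6987 CPM in astrocyte-like cells of the cortex sham library. Its 2560 CPM in pericyte-like cells there lay well above the 241 CPM in microglia-like cells, so RNA spread evenly over all cells does not give that level, and its source in vascular cells was not tested. Endothelial-like cells had the same order for Slc1a2, 327 against 2167 CPM under sham and 585 against 2097 CPM under DOCA-salt. Cpe is in the list of astrocyte RNA, and Fam107a was a leading gene of an astrocyte cluster. Astrocyte RNA can therefore carry their lower level in hippocampal vascular cells, which was not tested.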

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

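No test of an explanation was run for these 4 genes. Each was at least 1.5-fold apart in opposite directions in the tissues, with both intervals excluding no difference, and the difference between tissues was not tested. Those intervals leave out the spread between cells. Ccl4, a chemokine gene, stood at 0.559 times the sham level in hippocampal border-macrophage-like cells and at 2.41 times in cortical ones. Ccn2, a matrix-associated growth factor gene, stood at 0.457 times in hippocampal pericyte-like cells (0.244 to 0.826) and at 3.26 times in cortical ones (1.2 to 11.1). Gzma, which encodes granzyme A, stood at 3.88 times in hippocampal T- or NK-cell-like cells (2.87 to 5.35) and at 0.381 times in cortical ones (0.270 to 0.537). Ttr stood at 0.00789 times in hippocampal microglia-like cells and at 1.61 times in cortical ones, and the hippocampus sham library held 348 choroid plexus cells that make this transcript.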

How the results depend on the processing

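Of 261 share values under alternative settings 245 stayed within the interval of the chosen setting, 12 moved and 4 reversed. A setting gave no value where either library had no cells named as the class, and such losses are not in these counts. With libraries clustered alone only 20 of 35 shares had a value, of which 14 stayed, 5 moved and 1 reversed. Resolutions 0.5 and 2 gave 31 and 33 values. For gene lists the counts were 1180, 110 and 1 of 1291, and for named genes 570, 33 and 0 of 603. For hippocampus against cortex 118 of 118 stayed, but only TMM scaling and the stricter filter were run there. Where no construction is named, the cause was not tested. At resolution 0.5 the share ratio of DOCA-salt to sham was 2.09 for hippocampal astrocytes, 1.01 for hippocampal pericytes and 0.971 for cortical ones. With libraries clustered alone it was 1.43 and 1.03 for hippocampal and cortical endothelial cells and 1.18 and 0.893 for oligodendrocytes. Among immune cells hippocampal microglia stood at 0.958, and among non-immune cells hippocampal oligodendrocytes at 0.791. The mixed cycling cluster, added later, took hippocampal neutrophils to 0.810. No sub-clustering, also added later, gave 1.04 for hippocampal pericytes and 0.907 and 0.562 for hippocampal and cortical smooth muscle, and the stricter filter 0.218 for cortical smooth muscle. With no minimum of UMIs the median log2 ratio was 2.64 for cortical border macrophage MHC class II genes and 1.30 for cortical endothelial activation. Thinning gave 2.85 for those MHC class II genes, -0.41 for hippocampal endothelial heat shock and, for hippocampal corticosteroid targets, -0.061 in microglia, -0.24 in endothelial cells, -0.30 in astrocytes and -0.70 in oligodendrocytes. Totals without mitochondrial, ribosomal and haemoglobin genes gave 0.013 for cortical microglial complement. TMM scaling gave immediate early genes 0.57 in cortical astrocytes and 0.73 and 0.74 in hippocampal and cortical oligodendrocytes, and heat shock -0.31 in hippocampal endothelial cells, -0.33 in cortical astrocytes and -0.43 and -0.34 in oligodendrocytes. Without clusters held by 1 library, added later, heat shock in hippocampal oligodendrocytes was -0.39. A minimum of 100 UMIs gave corticosteroid targets -0.26 in hippocampal endothelial cells, -0.36 in hippocampal astrocytes and -0.78 in cortical oligodendrocytes. No paired analysis was possible because each group holds 1 library, the labels tie no library of a group to an animal of another, and no result comes from a test, and leaving out a replicate is not possible.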

Other observations

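Hippocampal microglia-like cells of the DOCA-salt library carried fewer hypoxia transcripts while endothelial-like cells carried more. The hypoxia list lay at -0.28 in hippocampal and 0.08 in cortical microglia-like cells, with Ndrg1 at 0.553 times the sham level in hippocampus, and at 0.14 and 0.15 in astrocyte-like cells. Transcripts encoded in mitochondria were higher in microglia-like cells, at medians of 0.43 and 0.45, higher in endothelial-like cells, at 0.38 and 0.21, and oligodendrocyte-like cells, at 0.24 and 0.25, and lower in astrocyte-like cells, at -0.45 and -0.52, and whether RNA quality differed was not tested. Nuclear genes of oxidative phosphorylation stayed at 0.05 and 0.16 in microglia-like and at -0.01 and -0.09 in astrocyte-like cells. Interferon gamma response genes had medians of 0.13 and 0.65 in oligodendrocyte-like cells, with Irf1, a transcription factor gene of that response, 1.73-fold and 1.77-fold higher. Adrenergic signalling genes, the receptors through which sympathetic nerves act, lay at -0.02 and 0.08 in microglia-like, 0.19 and 0.15 in endothelial-like and 0.22 and 0.13 in pericyte-like cells, with at most 8 of 12 members measured. Oxidative stress genes lay at -0.06 and 0.05 in microglia-like cells and complement genes at 0.08 and -0.02. Synapse genes in hippocampal immature neurons lay at 0.13, and cell cycle genes in microglia-like cells at -0.21 and 0.16.

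Of the tests that follow, the comparison of Lcn2 with neutrophil RNA, both tests of the wider set of 39 genes and the thinning test of hippocampal microglia alone were chosen only after the result was seen. A first pattern is a set of genes far apart in both tissues: Gm8797, Serpina3n and Arhgap6 higher and Zbtb16 lower by at least 4-fold in 3 or more classes. A strain or donor variant against the reference might place such genes close together on a chromosome, yet 0 of 4 had another within 1 Mb, which cannot decide because random sets also had a median of 0. In the wider set of 39 genes apart in at least 1 class, 6 had a neighbour against a random median of 2 and a 95th percentile of 6 (for genes apart between tissues 6 of 73, against a median of 8), so that a variant and an effect of treatment cannot be told apart, and chromosome 17 held 9 of them (23.1%, against 5.08% of measured genes), a count that was noticed and not tested. Reads shared between neighbouring paralogs predicted a neighbour of the same name stem that goes the opposite way. That was found for 0 of 4 and 1 of 39 genes (Cd59b beside Cd59a). Neighbours named as gene models were left out, so Gm8797 could not have one. How many genes had any neighbour of the same stem was not counted, so shared reads are not excluded. Copies elsewhere in the genome were not tested. A difference of depth predicted a loss on thinning, but 1.05 times the median difference remained. Random thinning leaves the expected proportions within a cell unchanged, so it tests only the weight of deeper cells and the loss of shallow ones. It cannot exclude depth otherwise, and an effect of DOCA-salt or of the single library preparation on these genes stays open.

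A second pattern is endothelial Lcn2, 35.4-fold higher in the hippocampus DOCA-salt library. At the proportions of neutrophil-like cells, RNA from neutrophils, which also make Lcn2, accounts for 3.68% of the endothelial Lcn2 UMIs (upper bound of counting error 4.27%). This comes from 792 S100a8 and S100a9 UMIs beside 708 of Lcn2 there, against 57214 beside 1883 in neutrophil-like cells. Microglia-like cells of that library held 835 of S100a8 and 1201 of S100a9 beside 103 of Lcn2, so the true percentage can be somewhat higher. A cluster held by 1 library does not account for it either, as the ratio without that cluster is 33.1. An acute-phase activation of vessels by DOCA-salt, or by another event in those animals such as infection, injury or handling, stays open and untested with 1 library per group, and so do a strain or donor variant and the library preparation, since Lcn2, Lrg1 and Ackr1 belong to the wider set. New DOCA-salt and sham animals, with Lcn2, Lrg1 and Ackr1 stained in vessel sections and plasma LCN2 measured, would separate a treatment effect from an event in single animals.

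A last pattern is the lower level of corticosteroid receptor targets, foremost Zbtb16, Tsc22d3 and Fkbp5. Sgk1 was lower in oligodendrocyte-like cells but stayed near the sham level in endothelial-like cells. Sampling at another time of day would shift clock genes of opposite phase apart, but their medians differed by 0.12 in hippocampus and 0.30 in cortex on the log2 scale, although Dbp was 1.90-fold higher in hippocampus and 1.23-fold in cortex and a smaller shift stays open. A difference of depth predicted a loss on thinning, but the median of the list medians over 5 classes was -0.33 after it. Before, it was -0.27 over all members and -0.25 over the members left after thinning. For the reason given above, thinning cannot exclude depth. These members kept -0.30 of -0.36 in astrocyte-like and -0.24 of -0.26 in endothelial-like cells of hippocampus. They kept -0.56 of -0.78 in oligodendrocyte-like and -0.28 of -0.28 in astrocyte-like cells of cortex. In hippocampus they went from -0.10 to -0.42 in pericyte-like and from -0.56 to -0.70 in oligodendrocyte-like cells. In cortex they went from -0.062 to -0.23 in microglia-like, -0.14 to -0.41 in endothelial-like and -0.24 to -0.35 in pericyte-like cells. In hippocampal microglia-like cells they went from -0.24 to -0.061 (-0.24 to 0.029). These medians were thus unstable under thinning, and depth stays open. A lower level of corticosterone under DOCA-salt, through feedback of the given steroid on the adrenal axis, could leave glucocorticoid receptor targets lower, and stress of the sham animals could do the same, and both remain untested. A strain or donor variant stays open for Zbtb16, which belongs to both gene sets above. It was not tested for Tsc22d3 or for Fkbp5, which lies on chromosome 17, the chromosome noted above. The single library preparation stays open for the whole list. Plasma corticosterone at a fixed hour, and Zbtb16 and Tsc22d3 after adrenalectomy with clamped corticosterone under DOCA-salt, would tell the steroid explanations apart.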
